A study of Mus musculus with 6 samples.

How the data were processed

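Gene expression was measured by RNA sequencing in immortalised mouse bone marrow-derived macrophages, a line of macrophages grown out of mouse marrow and kept dividing in culture. The 6 libraries comprised 3 with a short hairpin RNA against Pgam5 and 3 with a short hairpin RNA against Dnm1l, the gene of DRP1. All cells had received interleukin-4 at 10 ng/ml for 24 h. Per the labels' protocols, poly-A RNA was captured on oligo-dT beads, fragmented and copied into cDNA from random primers. The protocol names both a directional and a non-directional second-strand step, so the strand setting of these libraries is not given in the sources used here.

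The deposited values were FPKM (fragments per kilobase of transcript, scaled to each library's total), 1 value per gene and library for 54532 Ensembl gene identifiers. Per the submitters' processing notes, the tools were HISAT2 2.0.5 for alignment and featureCounts 1.5.0-p3 for counting, with the mouse build mm10. The annotation release and the formula behind the FPKM are not given in the sources used here. Gene symbols, coordinates and exonic lengths were taken from GENCODE M21, which is on the same build, and 54409 identifiers were matched to it while 123 were not. FPKM divides by each library's total, so a gene that takes many reads lowers the values of all others, and a read shared by near-identical genes can be lost from both.

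The deposited FPKM values were checked for whole reads. Each value multiplied by the exonic length and by 1 depth per library lay within 0.02 of a whole number for 96.1% of the values above 0 in every library. The depths that gave this were 17765131, 16326409 and 18313291 reads in the PGAM5 knockdown libraries and 16111281, 17686387 and 21933548 in the DRP1 knockdown libraries. Detection limits given below are the FPKM of 3 reads and cover counting error only.

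Groups followed the sample titles. Before averaging, libraries were compared in pairs. Pearson correlations of log2 values over genes were 0.993 to 0.995 within groups and 0.986 to 0.988 between groups. The chi-square per gene of the recovered reads was 2.47 to 6.83 within groups, so no pair of libraries differed by as little as sampling noise. PGAM5 knockdown library 3 stood apart, at 6.83 with library 1 and 5.06 with library 2 of its group. The other pairs within groups gave 2.47 to 2.86. The titles do not say whether the numbers 1 to 3 are separate cultures or different hairpins, so p-values measure only the spread between these samples, which may be technical.

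Genes with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided). Benjamini-Hochberg adjustment covered all 10634 genes tested and the threshold was an adjusted p of 0.05. Differences are given as PGAM5 knockdown minus DRP1 knockdown on the log2(FPKM + 1) scale, which understates the change of genes with low values. Folds are ratios of mean FPKM. Differences of single values were also put to an exact permutation test, which cannot give a two-sided p below 0.1 with 3 libraries against 3.

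Before the data were examined, 26 gene lists were written from textbook knowledge, covering macrophage activation, interferon response, mitochondria, metabolism, stress, cell cycle, lysosome and markers of other cell types. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, again with a correlation estimated from the residuals, and with fry. Counts of members that rose or fell are given with the adjustment over all genes and adjusted over the list alone. Genes are named by a rule fixed before the data were examined. The rule takes the targeted genes, up to 3 members per list with the largest differences past the threshold, and the 8 largest positive and 8 largest negative differences with no overlap of the groups. If no member of a list passed, its most abundant member is named. Up to 2 members of each list of another cell type are named if they passed. Predicted genes with Gm or Rik symbols were left out of that rule. Other named members are examples chosen after their values were seen. Near-identical sequence was searched with blastn 2.17.0, matching the longest transcript of each gene to transcripts of other genes at 97% identity or more over at least 100 bases.

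The steps were tested on simulated data for the comparison of PGAM5 with DRP1 knockdown. Reads were drawn for 10087 genes from the libraries' own means and depths, with 50 genes changed at each fold. Every gene was given the same spread between libraries beyond counting noise (dispersion 0.00051). Among changed genes, 72% of those changed 1.25-fold, 90% at 1.5-fold, 96% at 2-fold and 100% at 3-fold were recovered, and 6 of 185 calls were genes with no simulated change. Genes with a larger spread were not simulated and few genes were changed, so these shares can overstate performance on the real libraries.

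Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, median-ratio scaling, quantile normalization, the replicate number as a block, no variance trend, robust empirical Bayes and each library left out in turn. Limma's voom on the recovered reads and camera with an estimated correlation as an alternative to the preset one were added after seeing the data. Splicing, isoforms and antisense transcription were not analysed here. A non-targeting hairpin and unstimulated cells were not analysed here either, so each difference is between the 2 knockdowns under interleukin-4.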

Results

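The series asked what PGAM5, a protein phosphatase of mitochondria, does when macrophages take on an anti-inflammatory state. DRP1, the GTPase that divides mitochondria, was the other target. Transcript levels were measured in 6 libraries of immortalised mouse macrophages given interleukin-4, 3 with PGAM5 knockdown and 3 with DRP1 knockdown, at 16111281 to 21933548 reads each. Levels below are mean FPKM ± SD with n = 3 libraries per group.

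Each knockdown showed in its own gene. Pgam5 (ENSMUSG00000029500, chromosome 5, 110259130 to 110269913, minus strand, mm10) stood at 4.91 ± 0.31 FPKM in the PGAM5 knockdown and 17.2 ± 0.14 in the DRP1 knockdown, 3.5-fold lower (log2 difference -1.62, SE 0.047, limma adjusted p = 4.5e-06). Dnm1l (ENSMUSG00000022789, chromosome 16, 16312230 to 16358959, minus strand) stood at 17.9 ± 0.75 and 7.57 ± 0.55 FPKM, 2.36-fold higher in the PGAM5 knockdown (log2 difference 1.14, SE 0.056, limma adjusted p = 2.9e-05). All 3 libraries of each group lay on their own side, and the exact permutation p was 0.1 for both genes, the smallest the design allows. A lincRNA, Gm26718, matched 65.9% of the longest transcript of Pgam5. Its own level was 0 FPKM in all 6 libraries. Reads shared by 2 genes can be lost from both and the strand setting is not given. The 0 therefore does not tell whether Gm26718 was transcribed or whether Pgam5 lost reads to the match.

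Most tested interferon-stimulated genes and 10 of 22 pro-inflammatory genes were higher in the PGAM5 knockdown. Il1b, the gene of the cytokine interleukin-1 beta, was 4.66-fold higher, at 9.86 ± 1.17 against 2.12 ± 0.26 FPKM (log2 difference 1.80, limma adjusted p = 3.9e-05). Il6 stood at 4.78 ± 0.57 against 1.5 ± 0.26 FPKM, and Ptgs2, which encodes the prostaglandin synthase COX-2, at 148 ± 0.82 against 63.6 ± 0.89. Among interferon-stimulated genes, Ifi44 was 5.58-fold higher at 3.86 ± 0.15 against 0.69 ± 0.15 FPKM. Usp18, which damps interferon receptor signalling, was 2.39-fold higher, and Irf7, a transcription factor of the interferon response, 2.34-fold higher.

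By list, 11 of the 16 tested interferon-stimulated genes rose, 0 fell and 5 did not pass (12 rose and 0 fell adjusted over the list alone; median log2 difference 0.38, camera adjusted p = 4.5e-06). That call held with an estimated correlation (adjusted p = 0.045). Isg15, Rsad2 and Ifih1 were among those that did not pass. Without the expression filter 28 members gave 11 that rose and 1 that fell, with a median of 0.17 (camera adjusted p = 0.00015). Members below the filter included Ifit1 at 0.80 ± 0.16 against 1.16 ± 0.041 FPKM and Ifit3 at 0.19 ± 0.076 against 0.50 ± 0.098. Of 22 pro-inflammatory activation genes, 10 rose, 2 fell and 10 did not pass (11 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0045). The pro-inflammatory call was lost with an estimated correlation (adjusted p = 0.155), within a range of 0.00049 to 0.155 over its 17 alternatives. The chemokine genes Ccl3 (log2 difference 0.74), Ccl4 (0.72) and Ccl2 (0.58) rose, while Ccl5 (-0.45) and Acod1 (-0.34), the enzyme that makes itaconate, fell. Tnf (134 ± 4.63 against 135 ± 1.87 FPKM) and Nos2 (102 ± 3.94 against 102 ± 0.66) did not pass.

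**Figure D1:**
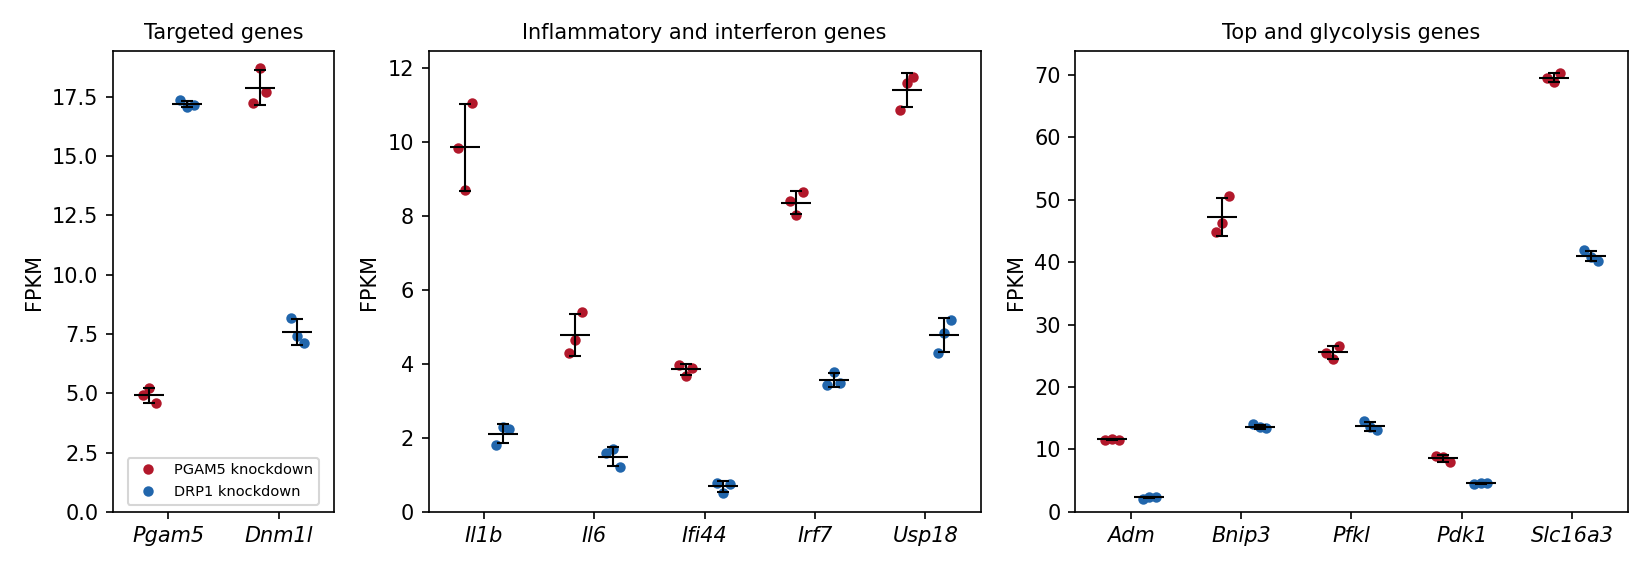
FPKM per library (points; horizontal line and bars, mean and SD of n = 3) of the targeted genes, of inflammatory and interferon genes and of strongly changed and glycolysis genes, in the PGAM5 knockdown (red) and the DRP1 knockdown (blue). Every gene shown except Pgam5 was higher in the PGAM5 knockdown, and for none of them did the 2 groups overlap.

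Genes known to respond to interleukin-4 were mostly near 0 in both groups. Of the 28 markers of alternative activation, 22 lay below the filter, the highest of these at a mean of 0.85 FPKM (Egr2). Retnla, Chil3, Ccl17 and 7 others had 0 reads in all 6 libraries, which allows at most the 3 reads taken as the detection limit per library. Arg1, the arginase that marks alternatively activated mouse macrophages, was at 0 to 0.11 FPKM, and the mannose receptor gene Mrc1 at 0 to 0.019 FPKM. Of the 6 tested members 1 rose, 2 fell and 3 did not pass, the same counts as adjusted over the list alone (camera adjusted p = 0.146, estimated correlation adjusted p = 0.276). With fry, which compares no list with other genes, the 6 moved down on balance (adjusted p = 0.0043). Ppargc1b, a mitochondrial coactivator gene, fell (2.94 ± 0.61 against 4.59 ± 0.15 FPKM, log2 difference -0.52, limma adjusted p = 0.014). Atp6v0d2, which encodes a subunit of the lysosomal proton pump, fell (-0.26) and Tmem26 rose (0.26). The adjusted p ranged from 0.0011 to 0.055 over 15 alternatives for Ppargc1b, lost without DRP1 knockdown library 1 or 2, and from 0.0040 to 0.075 over 16 for Tmem26, lost without library 1 or 3 of either knockdown. Il1rn, the most abundant member, measured 79.5 ± 0.76 and 82.0 ± 2.0 FPKM and did not pass.

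**Figure D2:**
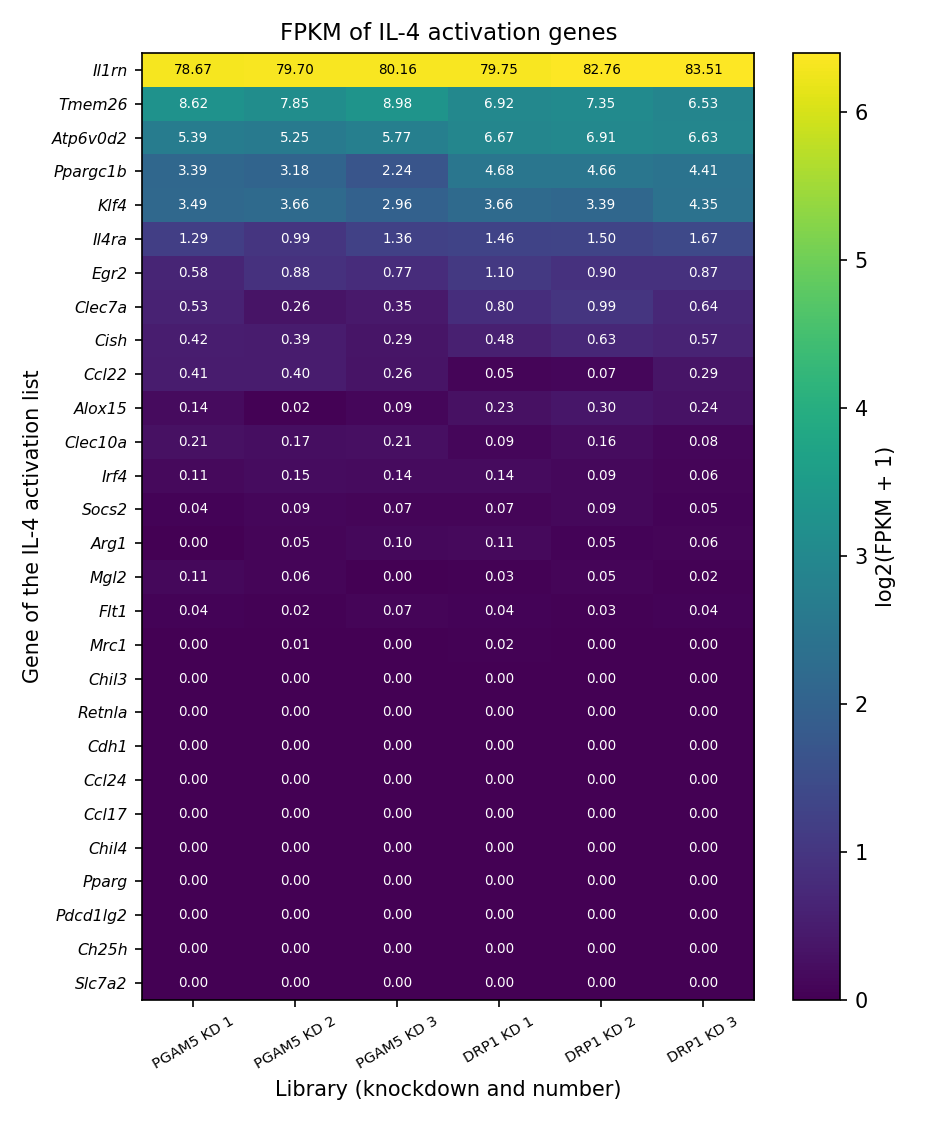
Heatmap of 28 interleukin-4 activation genes (rows) in the 6 libraries (columns, knockdown and number), with the FPKM printed in each cell and the colour giving log2(FPKM + 1). The 22 genes below the filter fill the lower rows, and Il1rn at 78.7 to 83.5 FPKM stands at the top.

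Glycolysis genes were higher in the PGAM5 knockdown. Of the 19 tested, 16 rose, 1 fell and 2 did not pass (16 rose and 2 fell adjusted over the list alone; median log2 difference 0.37, camera adjusted p = 3.0e-09, estimated correlation adjusted p = 0.041). Pfkl, the liver-type phosphofructokinase, stood at 25.6 ± 1.04 against 13.7 ± 0.74 FPKM, 1.86-fold higher (log2 difference 0.85, SE 0.049). Pdk1, the kinase that holds pyruvate dehydrogenase inactive, was 1.87-fold higher at 8.56 ± 0.54 against 4.57 ± 0.035 FPKM, and Slc16a3, a lactate exporter, 1.70-fold higher at 69.5 ± 0.75 against 41.0 ± 0.87. The glucose transporter gene Slc2a1 and Ldha each had a log2 difference of 0.75. Hk3, a hexokinase gene, fell (-0.48). Gapdh did not pass, with 4.10, 4.94 and 3.53 FPKM in the PGAM5 knockdown libraries and 3.98, 57.8 and 30.2 in the others, and 97 other genes matched part of its longest transcript.

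Among genes whose groups did not overlap, Gm and Rik symbols left out, the largest called increases were Adm, Il1b, Snord11, Bnip3, Tnfrsf13b, Cd5, Mir23b and Timp1. Adm, the gene of the peptide adrenomedullin, was 5.02-fold higher at 11.6 ± 0.068 against 2.31 ± 0.15 FPKM (log2 difference 1.93, SE 0.050, limma adjusted p = 3.7e-06). Bnip3, a receptor for removal of mitochondria, was 3.46-fold higher at 47.2 ± 3.00 against 13.7 ± 0.31 FPKM, and 94.2% of its longest transcript matched 4 other genes. Tnfrsf13b, the receptor TACI, was 5.61-fold higher and the surface protein gene Cd5 5.08-fold higher. Timp1, a metalloproteinase inhibitor gene, stood at 2.76 ± 0.37 against 0.24 ± 0.12 FPKM, which rests on 128 reads against 11. Few reads lay behind Snord11 (11 reads against 0, at least 3.86-fold higher against a floor of 3 reads over the DRP1 knockdown libraries) and Mir23b (14 against 2).

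By the same rule, the largest called decreases were Lyz1, Pgam5 itself, AU022793, Mir669n, Igf1, Gpnmb, Mcoln2 and Dok7. Lyz1, a lysozyme gene, was 5.91-fold lower at 4.29 ± 0.59 against 25.3 ± 0.25 FPKM (log2 difference -2.32, SE 0.075, limma adjusted p = 6.7e-06). Gpnmb, a membrane glycoprotein of lysosomes, was the most abundant of them, at 478 ± 4.4 against 1123 ± 5.5 FPKM. Igf1, the gene of insulin-like growth factor 1, stood at 0.24 ± 0.036 against 2.00 ± 0.13 FPKM, and the lincRNA AU022793 at 2.46 ± 0.21 against 9.24 ± 0.76. Mcoln2, an ion channel of endolysosomes, and Dok7, an adaptor of a muscle receptor kinase, had log2 differences of -1.12 and -1.09. Mir669n had 1 read against 7, and its adjusted p ranged from 0.0076 to 0.093 over 15 alternatives, the call being lost without library 2 or 3 of either knockdown.

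Lysosomal and macrophage-identity genes were lower in the PGAM5 knockdown. Of 27 lysosomal genes 1 rose, 18 fell and 8 did not pass (1 rose and 19 fell adjusted over the list alone; median log2 difference -0.15, camera adjusted p = 5.4e-07, estimated correlation adjusted p = 0.041). Besides Gpnmb, the protease genes Ctsf (13.9 ± 1.67 against 20.8 ± 1.5 FPKM) and Ctsd (446 ± 9.7 against 616 ± 16.6) fell. Ctsl was the 1 that rose, a call lost without DRP1 knockdown library 1, 2 or 3, with the replicate block, without the trend and without the expression filter (limma adjusted p of up to 0.089). Of 17 macrophage-identity genes 0 rose, 9 fell and 8 did not pass (0 rose and 11 fell adjusted over the list alone; median log2 difference -0.19, camera adjusted p = 3.9e-05, estimated correlation adjusted p = 0.043). Lyz2, the main lysozyme gene of macrophages, stood at 1272 ± 71.9 against 1954 ± 8.8 FPKM and Csf1r, the receptor for colony-stimulating factor 1, at 139 ± 4.7 against 212 ± 2.7. Cebpa, a transcription factor gene of the myeloid lineage, measured 1.47 ± 0.23 against 2.76 ± 0.54 FPKM. Spi1, Adgre1 and Cd14 did not pass.

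Of the respiratory chain, transcripts of the mitochondrial genome were lower and a part of the nuclear ones higher. Among 12 genes of the mitochondrial genome 0 rose, 8 fell and 4 did not pass (0 rose and 9 fell adjusted over the list alone; median log2 difference -0.45, camera adjusted p = 1.0e-06), and the call was lost with an estimated correlation (adjusted p = 0.155), in a range of 2.3e-08 to 0.155 over 17 alternatives. mt-Nd4 stood at 123 ± 3.8 against 173 ± 4.0 FPKM and mt-Nd2 at 176 ± 11.8 against 247 ± 6.3. A pseudogene matched 63.6% of mt-Nd4. mt-Nd3 was listed at 0.49 ± 0.26 against 1.86 ± 0.090 FPKM, with 99.1% of it matched by a nuclear pseudogene. The summed FPKM of the protein-coding mitochondrial genes was 3023 ± 63.0 against 4056 ± 93.3 (exact permutation p = 0.1). The nuclear list was written with 91 symbols, of which 76 were found in the annotation. Of these 76 nuclear genes 16 rose, 0 fell and 60 did not pass, with the same counts adjusted over the list alone (median log2 difference 0.078, camera adjusted p = 0.0033, fry adjusted p = 0.183). The list call was lost with an estimated correlation (adjusted p = 0.669) and without PGAM5 knockdown library 3 (0.163), in a range of 1.6e-05 to 0.669 over 17 alternatives. Its median was 0.028, with 3 that fell, without PGAM5 knockdown library 3, 0.120 without library 1 and 0.048 under quantile normalization. Cox7c (log2 difference 0.30), Ndufb9 (0.28) and Ndufs7 (0.26) had the largest differences of the 16 that rose. Over 16 alternatives the adjusted p reached 0.085 for Ndufb9, lost without PGAM5 knockdown library 2 or DRP1 knockdown library 1 or 3, and 0.05 for Ndufs7, lost without DRP1 knockdown library 3. Leaving out PGAM5 knockdown library 2 or DRP1 knockdown library 1, 2 or 3 gave 9, 9, 8 and 6 that rose. No expression filter, the replicate block and no trend gave 8, 9 and 11, while 23 rose without PGAM5 knockdown library 1.

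Lists on mitochondrial shape, mitophagy and lipids did not pass camera, while some of their members passed limma. By fry, which asks only whether a list moves on balance one way, fission and fusion (adjusted p = 0.037) and mitophagy (adjusted p = 0.0043) passed, and fatty acid oxidation (0.104) and cholesterol synthesis (0.320) did not. Of 27 fission and fusion genes besides the targets 2 rose, 1 fell and 24 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.243), while 4 rose without PGAM5 knockdown library 2 and with voom. The prohibitin genes Phb2 (92.9 ± 2.60 against 74.2 ± 1.51 FPKM) and Phb (log2 difference 0.26) rose, and Mff, a receptor for DRP1 on mitochondria, fell (9.30 ± 0.17 against 11.9 ± 0.28 FPKM). Other genes matched 51.5% of the longest transcript of Phb. Of 21 mitophagy genes 4 rose, 2 fell and 15 did not pass (6 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.36), with Vdac1 at 68.4 ± 5.72 against 49.3 ± 0.42 FPKM and Atg13 lower (-0.29). Of 25 fatty acid oxidation genes 2 rose, 4 fell and 19 did not pass, as they did adjusted over the list alone (camera adjusted p = 0.674), and 1 rose without PGAM5 knockdown library 3 or DRP1 knockdown library 2 or 3. The median of that list was 0.062, while its mean was -0.013 and its test pointed down. Lpl, Cpt1a, the enzyme that commits fatty acids to oxidation, and Lipa fell, with log2 differences of -0.45, -0.32 and -0.28. Of 22 cholesterol synthesis genes 3 rose, 1 fell and 18 did not pass (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.956). These counts were not stable, with 1 that rose without library 2 of either knockdown, PGAM5 knockdown library 1 or DRP1 knockdown library 3, and 0 to 2 that fell over the alternatives. Msmo1 (0.31) and Idi1 (0.26) rose and Hsd17b7 (-0.25) fell. Idi1 lost its call without PGAM5 knockdown library 1, 2 or 3 or DRP1 knockdown library 2 or 3, and Hsd17b7 without PGAM5 knockdown library 2 or DRP1 knockdown library 1 or 3, with limma adjusted p of up to 0.13 and 0.065 over 15 alternatives each.

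Stress lists split. Of 24 genes of the ATF4 stress response 10 rose, 3 fell and 11 did not pass (13 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.025). The ATF4 call was lost with an estimated correlation (adjusted p = 0.187) and under quantile normalization (0.470), in a range of 0.0012 to 0.470 over 17 alternatives. Under quantile normalization 8 rose and 6 fell, and the median log2 difference was 0.014 in place of 0.098. Ddit4, an inhibitor of the growth kinase complex mTORC1, stood at 147 ± 1.31 against 85.9 ± 0.93 FPKM, Gdf15 at 34.0 ± 1.16 against 23.3 ± 0.53, and the proline synthesis gene Pycr1 rose (log2 difference 0.37). Of 19 NRF2 antioxidant genes 3 rose, 8 fell and 8 did not pass (4 rose and 10 fell adjusted over the list alone; camera adjusted p = 0.041). The NRF2 call was lost with an estimated correlation (adjusted p = 0.155), under quantile normalization (0.121), with voom (0.120), and without PGAM5 knockdown library 3 (0.087) or DRP1 knockdown library 3 (0.055), in a range of 0.029 to 0.155 over 17 alternatives. Me1, malic enzyme, was 1.80-fold higher at 35.2 ± 1.27 against 19.5 ± 0.93 FPKM, while Gstm1 (-0.52) and the ferritin gene Ftl1 (-0.38) fell, the latter with 100% of its transcript matched by other genes. Of the longest transcripts of Me1 and Gstm1, 60.1% and 51.0% were matched by other genes.

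Of 28 cell cycle genes 14 rose, 0 fell and 14 did not pass, as they did adjusted over the list alone (median log2 difference 0.12, camera adjusted p = 1.0e-04, estimated correlation adjusted p = 0.043). Cdk1, the kinase of mitotic entry, rose (0.37), as did Tyms (0.32) and the replication helicase gene Mcm3 (44.1 ± 0.58 against 35.4 ± 1.07 FPKM), while Mki67, Plk1 and Ccnb1 did not pass. Without DRP1 knockdown library 1 or 2, 8 cell cycle genes rose. Tyms lost its call without PGAM5 knockdown library 2 or DRP1 knockdown library 1 or 2 (limma adjusted p of up to 0.059). Summed FPKM of genes with symbols beginning in Hist and a digit was 234 ± 2.1 against 291 ± 1.7 (exact permutation p = 0.1). The libraries were captured by poly-A tail, so this sum was not taken as a measure of replication. Of 17 p53 targets 4 rose, 3 fell and 10 did not pass (5 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.548), with Plk2 at 80.8 ± 0.65 against 52.1 ± 0.38 FPKM, Pmaip1 at 25 ± 0.33 against 15.9 ± 0.48 and Cdkn1a higher (0.32). Of 18 inflammasome and necroptosis genes 8 rose, 1 fell and 9 did not pass (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.181). With fry the p53 list (adjusted p = 0.0011) and the inflammasome and necroptosis list (adjusted p = 0.0021) passed, both pointing up. Ripk3, the kinase of necroptosis, was 1.44-fold higher at 18.2 ± 0.81 against 12.6 ± 0.47 FPKM, and Il18 (0.35) and Nlrp3 (0.26) rose. The Il18 call was lost with voom (limma adjusted p = 0.068). Casp1 was the 1 that fell (-0.17), a call lost under 7 of 16 alternatives, among them leaving out library 1 or 2 of either knockdown (limma adjusted p of up to 0.094).

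Few of the listed markers of other cell types reached the filter. Tnfrsf13b and Cd5, among the largest increases above, were on none of these lists, which say nothing about unlisted genes. No member of the fibroblast, neutrophil, mast cell and basophil, or erythroid lists reached the filter. Lck of the T cell list (7.21 ± 0.15 against 6.88 ± 0.16 FPKM), Ighm of the B cell list (26.2 ± 0.96 against 23.3 ± 1.65) and Bst1 of the dendritic cell list (3.09 ± 0.19 against 2.80 ± 0.32) were the only tested members of theirs and did not pass over all genes, while Ighm passed adjusted over the list alone. Of 5 osteoclast genes 2 rose, 1 fell and 2 did not pass (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.845, median -0.033, mean 0.045), and 1 rose without PGAM5 knockdown library 3 or any 1 DRP1 knockdown library. With fry the osteoclast list passed, pointing down (adjusted p = 0.0050). Mmp9, a secreted matrix protease, rose (3.16 ± 0.36 against 1.56 ± 0.27 FPKM), and Ctsk, cathepsin K, fell (96.6 ± 2.86 against 151 ± 1.88). Of the MHC class II list Cd74 alone was tested, at 1171 ± 32.1 against 1154 ± 27.4 FPKM (limma adjusted p = 0.677).

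**Figure D3:**
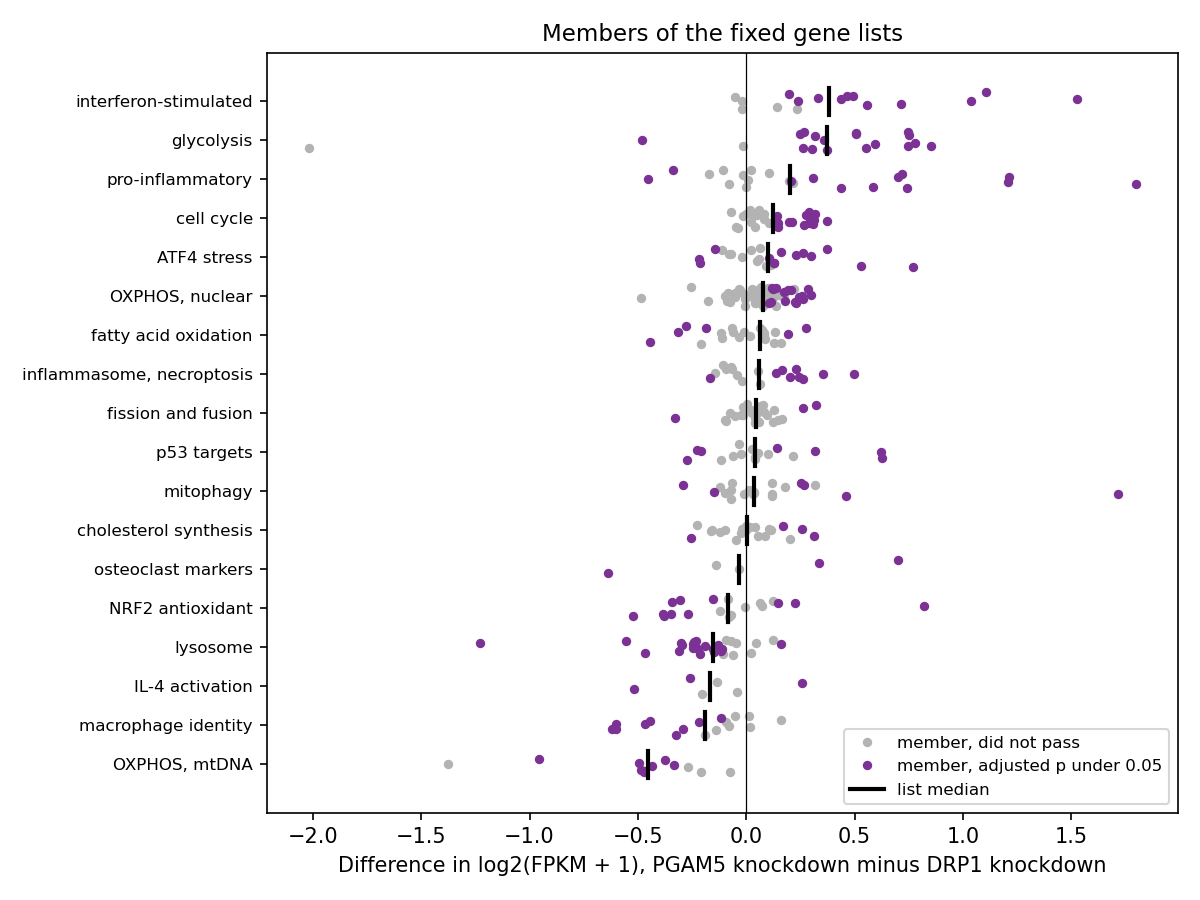
Difference in log2(FPKM + 1), PGAM5 knockdown minus DRP1 knockdown, of each tested member (points; purple, adjusted p under 0.05; grey, did not pass) of 18 gene lists, with a black bar at each list's median. The medians run from 0.38 for interferon-stimulated genes to -0.45 for genes of the mitochondrial genome.

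Over all 10634 genes tested with limma, 2704 (25.4%) differed, 1464 of them higher and 1240 lower in the PGAM5 knockdown, with a median absolute log2 difference of 0.26. Of these, 43 differed by at least 1 on the log2 scale, 32 higher and 11 lower. The groups did not overlap in 4629 genes (43.5%, against 10% by chance). Of 18 lists tested, 10 were called, 6 up and 4 down, and 5 with an estimated correlation. By fry, which compares no list with other genes, 15 of the 18 moved on balance one way. The count of genes was 1798, with 971 higher, without DRP1 knockdown library 2, and 825 were lower without DRP1 knockdown library 3. The count of 43 became 96 with a pseudocount of 0.1, 22 at a mean FPKM of at least 5, and 102 with voom on recovered reads.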

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

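Voom on recovered reads and camera with an estimated correlation were chosen after seeing the data. Pgam5 and Dnm1l kept their direction and stayed past the threshold under all 16 alternatives, at log2 differences of -1.81 to -1.59 and 1.10 to 1.246. The 2704 genes became 2133 with the replicate number as a block, and the block changed the call of no list as a whole but of some genes named here, among them Tmem26, Mir669n, Ctsl, Casp1 and Bhlhe40. No pairing by number was seen in the values. The deviations of same-numbered libraries correlated at 0.021, 0.031 and -0.00034, and not every library correlated best with its own number. These correlations cannot tell whether same-numbered libraries were handled as pairs. Leaving out 1 library at a time gave 1798 to 2738 genes, 971 to 1458 of them higher and 825 to 1280 lower, and 8 to 10 lists; each such fit had fewer libraries. Of genes differing by at least 1 on the log2 scale, 43 became 96 with a pseudocount of 0.1, which compresses low genes less, 22 at a mean FPKM of at least 5, which tests 7154 genes, and 102 with voom, which called 3017 of 10087 genes. The share of calls that were higher was 54.1%, 50.8% under median-ratio scaling and 49.0% under quantile normalization. Called lists fell from 10 to 5 with an estimated correlation. Cd74 had a log2 difference of -0.064 with an adjusted p of 0.032 under quantile normalization, in a range of 0.032 to 0.990 over 15 alternatives. For voom, the estimated correlation and Cd74 the cause was not tested. Among genes named by the fixed rule Ppargc1b, Tmem26, Ndufb9, Idi1, Hsd17b7, Tyms, Mir669n, Il18 and Ndufs7 lost their call under 1 or more alternatives, at most 7 under 1 of them, which was no expression filter (21552 genes tested), and none of these turned direction. Outside that rule Ctsl, Casp1 and Bhlhe40 lost theirs under 6, 7 and 4 of 16 alternatives. Mir669n and Snord11, only 54 and 84 bases long, rested on a handful of reads. Longer genes near 1 FPKM had more, such as Il4ra with 904 reads over the 6 libraries at a mean of 1.38 FPKM.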

Other observations

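The tests on genes of the interleukin-4 receptor and on shuffled neighbours, the grouping of genes by symbol family and the list of hypoxia genes were chosen after results had been seen. Of the 8 tested genes with symbols beginning in H2-, the prefix of the mouse major histocompatibility complex, 6 were higher in the PGAM5 knockdown and 0 lower (median log2 difference 0.33, camera adjusted p = 0.010 over symbol families of at least 5 tested members). That call was lost with an estimated correlation (adjusted p = 0.963). H2-T24 and H2-T23 had log2 differences of 0.98 and 0.85. The class II genes H2-Eb1 and H2-Ab1 lay below the filter and were not tested, H2-Eb1 at 1.14 to 1.76 against 0.21 to 0.24 FPKM and H2-Ab1 at 0 in each of 3 libraries against 0.19 to 0.31. Gm23935, a 57-base gene annotated as a miRNA, took 10.5 to 13.7% of the summed FPKM of a library. This share reflects division by its short length. It held 35318 reads of 16111281 in DRP1 knockdown library 1 and 63236 of 21933548 in DRP1 knockdown library 3.

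Known targets of the hypoxia-inducible factor HIF, written down after Adm, Bnip3 and the glycolysis genes had been seen, were higher too. Of 37 tested members 31 were higher, 1 lower (Bhlhe40, log2 difference -0.18) and 5 did not pass. The Bhlhe40 call was lost under 4 of 16 alternatives. Egln1, the oxygen-sensing hydroxylase that marks HIF for degradation, stood at 12.7 ± 0.43 against 6.28 ± 0.49 FPKM, Ak4 at 8.25 ± 0.24 against 4.32 ± 0.054 and Vegfa at 46.2 ± 0.62 against 36.7 ± 0.53 (SD, n = 3).

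The higher glycolysis genes were weighed first. A shift of the overall scaling is argued against by a list median of 0.346 under the scaling that lowered it most, and reads shared with gene copies by a median of 0.432 over the 12 members with under 5% of their transcript matched elsewhere. A candidate explanation is a HIF-type programme that was higher in the PGAM5 knockdown. Among 28 HIF targets outside the fixed lists whose values had not been seen, the median log2 difference was 0.337, with 22 higher and 1 lower (camera p = 1.9e-12, and p = 0.0014 with an estimated correlation). Whether such a programme would come from the knockdowns or from cell density or oxygen in the cultures was not tested.

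Low interleukin-4 markers in all libraries were weighed next, over the 22 members below the filter. Depth is argued against, since 3 reads would make at most 0.362 FPKM for any of them and 13 stayed below 0.1 FPKM in all libraries, and 0 of the 22 had 50% or more of the longest transcript matched by another gene. Missing transcription of the receptor pathway is argued against by a lowest mean of 1.38 FPKM (Il4ra) among Il4ra, Il2rg, Jak1, Jak3 and Stat6. Stat6 stood at 39.3 ± 1.90 and 38.5 ± 0.70 FPKM. The cut-off for this was set after values had been seen, and a low level of the receptor is not argued against. Il4ra stood at 1.21 ± 0.20 against 1.54 ± 0.11 FPKM and did not pass. Il2rg was lower in the PGAM5 knockdown, at 21.3 ± 0.82 against 24.2 ± 0.67 FPKM (limma adjusted p = 0.017). A line that may respond weakly to the cytokine, or a weak dose, stays open, since unstimulated cells were not analysed here. A non-targeting hairpin was not analysed either, so low markers caused by both knockdowns alike stay open too.

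Changed genes lay next to each other on the chromosome more often than shuffled positions gave. Among 145 genes past the threshold with an absolute log2 difference of at least 0.7, 7 neighbouring pairs changed the same way, against a mean of 0.996 in 10000 shuffles (permutation p = 0.0003), which argues against chance. Overlapping annotation covers 1 of the 7 pairs, Rnase4 and Ang, which argues against reads counted for both genes as the whole cause. The 7 included Ccl9 with Ccl3, Ccl3 with Ccl4 and H2-T24 with H2-T23, neighbours within gene families. Also among them were Lrp12 with AU022793, and Gpnmb with Gm19253, 700 bases apart on the same strand. The shuffles treated family members as unrelated genes, so they do not separate family clusters from other neighbours. The pair Dmwd and Dmpk on chromosome 7, 1072 bases apart, had log2 differences of 1.29 and 1.39, while Six5, the gene that follows Dmpk, lay below the filter (0.16 ± 0.090 and 0.094 ± 0.042 FPKM). Sympk, further off on the other side, measured 33.6 ± 0.78 and 33.0 ± 0.51 FPKM. Shared local regulation may underlie such pairs, and an effect of the integrated hairpin vector near Dmwd could not be examined with these values.

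With 3 libraries against 3 there are 10 splits of the libraries, too few for a share under 0.05. The real split gave 2704 genes and the highest of the others 1, so 1 of the 10 splits reached the real count. Every other split put libraries of both knockdowns on each side. The difference between the knockdowns then counts as spread, which keeps the gene count low, so the contrast with 2704 says nothing about chance. For genes differing by at least 1 on the log2 scale the counts were 43 against 1, and for gene lists 10 against 6, again with 1 split as large. The split with 6 lists called by camera at the preset correlation had 0 genes called.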
